A study of Gallus gallus with 8 samples.

How the data were processed

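Gene expression was measured on Agilent one-colour chicken gene expression arrays in DT40 cells, a chicken bursal B cell lymphoma line that goes on diversifying its immunoglobulin genes in culture. The series holds 8 arrays in 3 groups: 3 of wild-type cells (WT), 2 of cells without BCL6 (BCL6KO) and 3 labelled as lacking both IRF4 and BCL6 (DKO). BCL6 is a transcriptional repressor of germinal centre B cells, and IRF4 is a transcription factor that B cells need to become plasma cells. The extraction protocol given with the samples speaks of independent cultures of WT and IRF4KO cells and names neither BCL6KO nor DKO cells, so whether the arrays of these groups came from separate cultures is not known. The labels give biotin as the label, while the labelling protocol describes Cy3.

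Per the file headers, each scanner file gives the processed signal of every spot as an intensity on a linear scale, background-subtracted and detrended within its array by Agilent Feature Extraction, with no normalization between arrays. Version 10.7.1.1 was used for the WT and DKO arrays and version 10.7.3.1 for the BCL6KO arrays. The same files hold the median spot and background signals as intensity and, per the file headers, flags for spots well above background, saturated or outlying. A value table deposited by the authors also holds intensity on a linear scale, with processing notes that name limma and R 2.12.0 but neither the order of steps nor their settings. Its 8 columns form 2 sets that were normalized separately, since the 5 columns labelled BCL6KO and DKO share a single distribution of values (within 0.01 log2) and the 3 columns labelled WT share another. The value table was log2-transformed and used as an alternative only, because several of its columns do not follow the scanner file of the same label.

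Values were taken as log2 of the processed signal minus the 75th percentile of the array, and are called log2 levels below. Of 43803 spots that were not controls, 43603 were different probes. Gene names came only from matching probe accessions to the RefSeq table for chicken, which named 10857 probes with 5005 symbols. The remaining 32746 probes, 17397 of them designed on Ensembl transcripts, kept their own identifiers. PRDM1, which encodes BLIMP-1, and BACH2 had no matched probe, so no value is given for either. A probe was kept when well above background on at least 2 of the 8 arrays, which left 34229 probes. Of the 31523 gene entries on the array, 24136 were tested with a single probe each, the probe with the highest mean over all arrays, and 4343 of these carried a gene symbol. Of 6294 entries with more than 1 probe passing, probes were called in opposite directions in 216 for BCL6KO against WT, 45 for DKO against WT and 191 for DKO against BCL6KO. None of the genes named by the rule given below is among them.

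A single limma model (limma 3.58.1, R 4.3.3, data.table version 1.17.8) was fitted with a mean per group, and 3 contrasts were tested with moderated statistics on 5 residual and 1.584 prior degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. These p-values measure the spread between the samples at hand, pooled over the 3 groups, and the number of arrays limits their precision. The BCL6KO pair differed more (SD of log2 differences 0.652) than pairs within WT or within DKO (0.442 to 0.486). The pooled spread rests mostly on the WT and DKO arrays and may understate that of BCL6KO. It also carries the spread of the BCL6KO arrays into DKO against WT, and may overstate the spread there. Where every array of a group read not well above background, the fold against that group is a bound. It sets the mean of the other group against the dimmest signal of each array still counted as well above background. Where the probe itself read higher than that, its own level was used. Such a fold is written "at least" and holds for the processed signal alone, since another background correction gave smaller changes for some of these genes. Where only some arrays of a group were well above background, the number of these arrays is given in place of the size of the change. Bounds have no order, so genes that carry them are named without ranking.

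Choices of groups, tests, lists and named genes were made before the data were examined. Of 24 gene lists, the pair of targets was read gene by gene and 23 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01. The 69 list tests were adjusted together. The lists were plasma cell genes, B cell identity, B cell receptor signalling, immunoglobulin diversification, unfolded protein response and ER folding, ER translocation and transport, N-glycosylation, antigen presentation, interferon response, BCL6 target genes, NF-kB targets, cell cycle, MYC and ribosome biogenesis, glycolysis and hypoxia, oxidative phosphorylation, ATF4 and amino acid response, sterol and lipid synthesis, adhesion and migration, apoptosis, and markers of T and NK cells, myeloid cells, erythroid cells and thrombocytes, and stromal cells. Named genes were IRF4 and BCL6, a fixed panel (PRDM1, XBP1, JCHAIN, PAX5, BACH2, EBF1, MYC), the 8 called genes with a symbol and no overlap between arrays with the highest and the 8 with the lowest fitted log2 change in each contrast, and up to 2 members per direction of each list described. For genes that changed and changed back, the 6 with the largest smaller fitted change of both contrasts were named. Fitted changes served only to pick genes and give no order where the fold is a bound. Some genes that this rule takes are not reported here.

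Data were simulated with the same 3 groups and 23847 genes, most of them unchanged, and with a single spread per gene for all groups. The recoveries and false calls therefore do not cover BCL6KO arrays that vary more than the others, nor data with most genes changed. Sets of 200 genes changed by 1.5-fold, 2-fold or 4-fold were recovered at 38.5%, 71.5% and 89% for BCL6KO against WT, with 19 false calls. The recoveries for DKO against WT were 48%, 68.5% and 94.5%, with 20 false calls, and those for DKO against BCL6KO were 42.5%, 71.5% and 87.5%, with 19. A simulated list of 25 genes shifted by 1 log2 unit was called in each contrast with the preset and with an estimated correlation, and 0 of 40 unchanged lists were called. The simulated genes were drawn independently of each other, so these list results do not cover lists whose genes are correlated.

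The WT and DKO arrays were scanned in the same session, with WT and DKO arrays together on 2 slides. The BCL6KO arrays lay on slides of their own in another session, so for both contrasts that involve BCL6KO the session cannot be told apart from the genotype. The replicate numbers shared by groups did not pair the arrays, since deviations from the group means of same-numbered arrays correlated across genes at -0.058 to 0.047.

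Alternatives planned with the design were normexp background correction (offset 50), quantile normalization, scaling by the median, the authors' value table, no filter on dim probes, a filter for all 8 arrays, the mean of all probes of a gene, fits of the compared groups alone, limma-trend with robust variance, array weights, the replicate number or the slide as a block, a minimum fold of 1.5 (treat), leaving out each array, an estimated correlation in camera, and fry. For normexp the median spot signal stood in for the mean spot signal, a column the scanner files lack. Cyclic loess, the slide as a fixed block, normexp with repaired background values and separate BCL6KO arrays for each contrast were chosen after seeing the data. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.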

Results

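Expression of chicken genes was measured in DT40 B cells on 8 arrays, 3 WT, 2 BCL6KO and 3 labelled DKO (IRF4 and BCL6). The arrays read 43803 spots each. Between 27332 and 29877 spots (62.4% to 68.2%) were well above background on the WT arrays, 28802 to 29716 (65.8% to 67.8%) on the DKO-labelled arrays and 32889 to 34683 (75.1% to 79.2%) on the BCL6KO arrays. The dimmest log2 level still well above background was -7.97 and -7.38 on the BCL6KO arrays, against -6.86 to -6.05 on the others. Dimmer spots thus passed on the BCL6KO arrays, so the shares do not count expressed genes alike, and bounds differ between groups. The 75th percentile of the signal was 2930 to 3099 intensity units for WT, 2550 to 2600 for DKO and 1924 to 2195 for BCL6KO, and 0 spots were saturated. Across genes, which are not independent replicates, Pearson's r between arrays was 0.993 to 0.994 within WT, 0.992 to 0.993 within DKO and 0.984 for the BCL6KO pair. Between groups r was 0.916 to 0.921 for DKO with WT, 0.874 to 0.880 for BCL6KO with WT and 0.876 to 0.883 for BCL6KO with DKO.

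The targeted genes were read first. IRF4 had a log2 level of 3.01 ± 0.13 (SD, n = 3) in WT, 5.09 ± 0.42 (n = 2) in BCL6KO and -1.72 ± 0.06 (n = 3) in the arrays labelled DKO. It was 4.23-fold higher in BCL6KO than in WT (log2 change 2.08 ± 0.18 SE) and stood at 3.77% of the WT signal in DKO, 26.6-fold lower. A second IRF4 probe was not well above background on any DKO-labelled array, at least 10.2-fold below WT and at least 38.4-fold below BCL6KO. BCL6 had a log2 level of 2.56 ± 0.03 in WT, -4.73 ± 0.33 in BCL6KO and 0.81 ± 0.14 in DKO. It was 156-fold lower in BCL6KO than in WT (log2 change -7.29, -7.58 to -4.47 over alternatives on the scanner files), while the arrays labelled DKO held 29.7% of the WT signal, 3.36-fold lower than WT and 46.5-fold higher than BCL6KO. Over the same alternatives the log2 change of BCL6 ran from -2.97 to -1.68 in DKO against WT and from 2.76 to 5.84 in DKO against BCL6KO. Normexp as planned put BCL6 in DKO against BCL6KO at a log2 change of 2.76 (adjusted p = 0.0729) and in DKO against WT at -1.71 (adjusted p = 0.314), both uncalled. With repaired background values, chosen after seeing the data, the changes were 4.38 and -1.71 and both were called. The 3 BCL6 probes measured in every group were 3.36-fold to 3.71-fold lower in DKO than in WT. The remaining BCL6 probe was not well above background in BCL6KO or DKO, at least 49.3-fold and at least 21.3-fold below WT. IRF4 signal was thus lowest in the arrays labelled DKO, whereas the BCL6 signal of 3 of 4 probes in these arrays lay between those of WT and BCL6KO. In the authors' value table, columns labelled DKO read IRF4 and BCL6 above columns labelled WT, and several of its columns do not follow the scanner file of the same label.

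**Figure D1:**
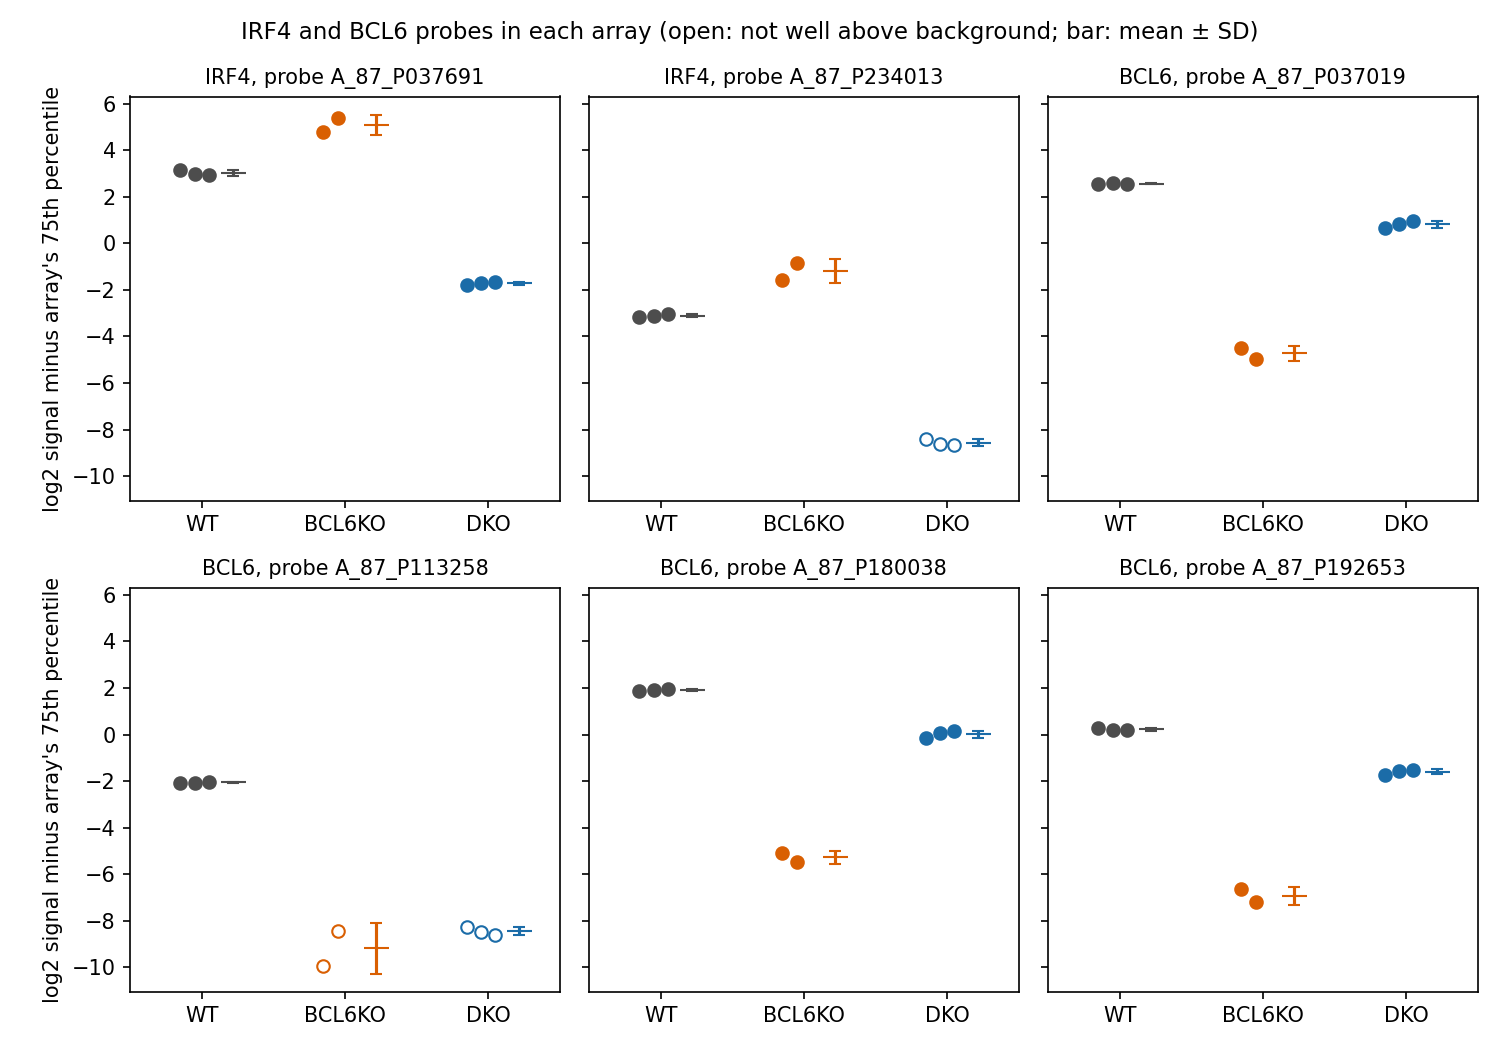
Log2 level (log2 signal minus the array's 75th percentile) of the 2 IRF4 probes and the 4 BCL6 probes, a panel each, on every array by group, with the mean and SD of the group; open points were not well above background. Both IRF4 probes are lowest on the DKO-labelled arrays (mean -1.72 for the probe tested), and 3 BCL6 probes lie between BCL6KO and WT there (0.81 for the probe tested, against -4.73 and 2.56), while the other BCL6 probe is at background in both.

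The comparison of BCL6KO with WT asks what loss of BCL6 changes in these B cells. PAX5, the factor that maintains B cell identity, was at least 30.8-fold lower (adjusted p = 1.68e-07). EBF1, another B lineage factor, was lower (adjusted p = 1.46e-05) and well above background on 1 of the 2 BCL6KO arrays. JCHAIN, which joins polymeric immunoglobulins, was 4.92-fold higher (log2 change 2.30 ± 0.10 SE, adjusted p = 3.1e-06), and MYC was 1.93-fold higher (adjusted p = 8.67e-05). Normexp as planned ended the calls of PAX5 (log2 change -0.42, adjusted p = 0.757), EBF1 (adjusted p = 0.0663) and MYC (0.44, adjusted p = 0.113), and all 3 were called with repaired background values. XBP1, a transcription factor of the unfolded protein response and of plasma cells, had a log2 change of 0.61 ± 0.17 (adjusted p = 0.0148). Scaling by the median (0.32), normexp as planned (0.17) and a minimum fold of 1.5 left XBP1 uncalled, leaving out BCL6KO array 2 left it at 0.31 and called, and its adjusted p over all alternatives on the scanner files ran from 0.000146 to 0.78.

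Among B cell identity genes, 20 of 26 fell and 5 rose (camera adjusted p = 8.49e-07, with an estimated correlation adjusted p = 0.109, range over alternatives tested with camera 1.6e-08 to 0.109). CD72, an inhibitory coreceptor of B cells, was lower (adjusted p = 4.78e-06) and well above background on 1 of the 2 BCL6KO arrays, and TLR7, a sensor of single-stranded RNA, was at least 459-fold lower. TCF3, which encodes the E2A factors, rose 5.74-fold, and CHIR-AB1, a chicken immunoglobulin Fc receptor, was at least 3.39-fold higher. Among genes of B cell receptor signalling, 20 of 30 fell and 5 rose (adjusted p = 2.64e-05, with an estimated correlation adjusted p = 0.493, range 4.61e-10 to 0.493). PTPN6, the phosphatase SHP-1, fell 816-fold (log2 change -9.67, -10.07 to -6.34 over alternatives) and CD79B, a signalling chain of the receptor, fell 439-fold (-8.78, -9.07 to -7.34). The kinase gene FYN was at least 17.2-fold higher and JUN rose 2.18-fold. Of 28 genes of immunoglobulin diversification, 17 fell, among them RAD54B (9.04-fold), and 6 rose, among them TCF3 and APEX1 (2.51-fold). The list had an adjusted p of 0.00617, with an estimated correlation adjusted p = 0.728 (range 1.48e-05 to 0.728).

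Of 50 cell cycle genes, 39 fell and 5 rose (adjusted p = 5.3e-08, with an estimated correlation adjusted p = 0.714, range 2.94e-16 to 0.714). The kinase gene CDK6 fell 22.1-fold (log2 change -4.46, -4.76 to -2.57 over alternatives), and CDKN2B, which encodes a CDK inhibitor, was at least 7.59-fold lower. Cyclin E1 (CCNE1) rose 4.38-fold and cyclin D2 (CCND2) 1.95-fold. In the unfolded protein response and ER folding list, 20 of 25 genes rose and 2 fell (adjusted p = 0.0136, with an estimated correlation adjusted p = 0.851, range 0.00027 to 0.851). CREB3L2, an ER-anchored transcription factor also held by the plasma cell list, rose 82.1-fold (log2 change 6.36, 5.12 to 6.68 over alternatives), and SEL1L, of ER-associated degradation, rose 7.44-fold. ERO1B, an ER oxidase, fell 3.32-fold. The ER folding list lost its call (adjusted p = 0.0623) in normexp with repaired background values, an alternative chosen after seeing the data. Among N-glycosylation genes, 13 of 15 rose and 0 fell (adjusted p = 0.00946, with an estimated correlation adjusted p = 0.851, range 0.00027 to 0.851), including FUT8 (2.48-fold), which adds core fucose, and DDOST (2.4-fold), a subunit of the oligosaccharyltransferase. Of 14 plasma cell genes, 9 rose and 4 fell, and the list was not called (adjusted p = 0.478). SUB1 rose 7.49-fold, while CD38 fell 10.1-fold (log2 change -3.34, -4.00 to 0.56 over alternatives) and the chemokine receptor gene CXCR4 fell 7.41-fold (-2.89, -3.29 to -0.44).

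Genes with large rises included PARVB, an adaptor of focal adhesions (at least 1442-fold), DIO2, a thyroid hormone deiodinase (at least 619.5-fold), the cadherin gene CDH11 (at least 584-fold), SYNM, an intermediate filament protein (at least 209-fold), EDIL3 (at least 146-fold) and CTTNBP2 (at least 121-fold). HPGDS, a prostaglandin D synthase, also rose (adjusted p = 5.81e-05) and was well above background on 2 of the 3 WT arrays, and PFKM, a phosphofructokinase, had a log2 change of 9.05 ± 0.22 (7.31 to 9.31 over alternatives). Large falls included those of F2RL1, a protease-activated receptor (at least 1448-fold), RDM1 (at least 419-fold), KCNK7 (at least 396-fold), RASSF2 (log2 change -10.76 ± 0.13), MYO1G (-10.18 ± 0.16), the common cytokine receptor chain IL2RG (-9.98 ± 0.11) and TRIM39.2 (adjusted p = 7.37e-07, well above background on 1 of the 2 BCL6KO arrays). Over alternatives, RASSF2 ran from -11.23 to -7.51, MYO1G from -10.67 to -6.09 and IL2RG from -10.39 to -7.03.

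In all, 16807 of 24136 genes were called in BCL6KO against WT, 10131 higher and 6676 lower (60.3% higher), and the median of all genes was 0.24. Of those with a symbol, 1627 rose and 1504 fell. Scaling by the median moved the median of all genes to -0.05 and the share that rose to 45.3%, and cyclic loess, chosen after seeing the data, gave 49.5%, so which direction holds more genes depends on the scaling. With a minimum fold of 1.5 the count was 8604, and normexp as planned gave 6876, because of 18 spots with an aberrant background on BCL6KO array 1 (18903 with these repaired). Beside the genes named above, normexp as planned reversed CDKN2B and CD38 and ended the calls of RDM1, KCNK7, CHIR-AB1, JUN, DDOST, CXCR4 and the lists of ER folding and N-glycosylation. With the repaired values all of these but the ER folding list were called in the direction given. Scan session and genotype cannot be told apart here.

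**Figure D2:**
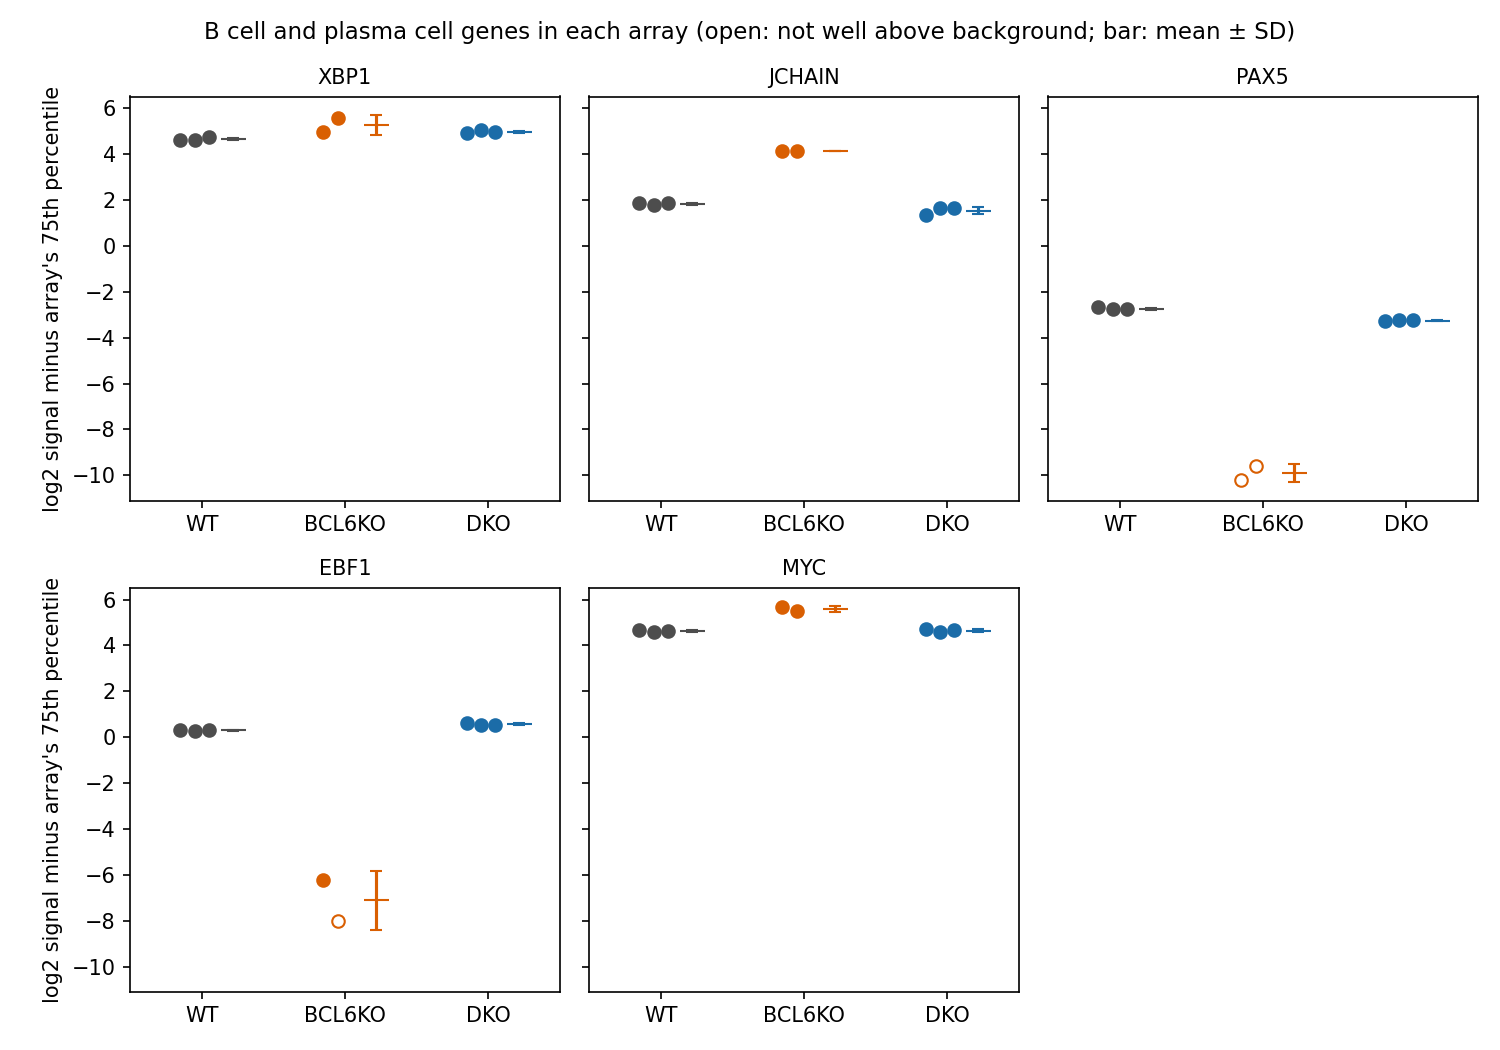
Log2 level (log2 signal minus the array's 75th percentile) of XBP1, JCHAIN, PAX5, EBF1 and MYC on each array, by group, with mean and SD; open points were not well above background. PAX5 and EBF1 are low on the BCL6KO arrays alone (means -9.90 and -7.11), and JCHAIN is highest on BCL6KO arrays (4.13).

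The comparison of DKO with BCL6KO asks what the further loss of IRF4 changes in cells that lack BCL6, with the limit that the arrays labelled DKO held 46.5-fold more BCL6 signal than the BCL6KO arrays. PAX5 was at least 21.5-fold higher (adjusted p = 2.79e-07), and EBF1 was higher (adjusted p = 1.39e-05). JCHAIN fell 6.04-fold (adjusted p = 2.06e-06) and MYC 1.91-fold (adjusted p = 0.000101). Normexp as planned ended the calls of PAX5 (adjusted p = 0.987), EBF1 (0.0617) and MYC (0.131), and all 3 were called with repaired background values. XBP1 (log2 change -0.31 ± 0.17 SE, adjusted p = 0.145) was not called. It was called without BCL6KO array 1 (-0.61, adjusted p = 0.000751) and under cyclic loess, chosen after seeing the data (-0.40, adjusted p = 0.0284). It stood at -0.0038 without array 2 and at 0.19 in normexp as planned, uncalled in both. Over all alternatives its adjusted p ran from 0.000751 to 1.

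Of 26 B cell identity genes, 18 rose and 6 fell (camera adjusted p = 7.06e-05, with an estimated correlation adjusted p = 0.133, range over alternatives tested with camera 4.79e-06 to 0.133). CD72 was higher (adjusted p = 2.48e-06) and well above background on 1 of the 2 BCL6KO arrays, and SPI1, which encodes the transcription factor PU.1, was at least 271-fold higher, while EAF2 fell 4.86-fold and TCF3 4.34-fold. Among 30 genes of B cell receptor signalling, 20 rose and 6 fell (adjusted p = 0.000742, with an estimated correlation adjusted p = 0.599, range 3.57e-06 to 0.599). PTPN6 rose 598-fold (log2 change 9.22, 5.87 to 9.59 over alternatives) and CD79B 204-fold (7.67, 6.30 to 7.85). FYN (log2 change -0.88 ± 0.22) and STIM1 (-0.82 ± 0.07), a calcium sensor of the ER, fell, and FYN lost its call under cyclic loess (-0.43), array weights (-0.86), a minimum fold of 1.5 and normexp as planned (-1.60), and without BCL6KO array 1 (-0.83, adjusted p = 0.054, range over alternatives 1.52e-05 to 0.302). Of 50 cell cycle genes, 34 rose and 6 fell (adjusted p = 1.04e-05, with an estimated correlation adjusted p = 0.851, range 2.43e-13 to 0.851). CDK6 rose 9.14-fold (log2 change 3.19, 1.31 to 3.38 over alternatives) and CDKN1B, a CDK inhibitor gene, 4.48-fold. CCNE1 fell 3.86-fold and CDKN1A, another CDK inhibitor gene, 3.48-fold (log2 change -1.80, -2.41 to -1.24 over alternatives).

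In the unfolded protein response and ER folding list, 21 of 25 genes fell and 0 rose (adjusted p = 0.00105, with an estimated correlation adjusted p = 0.851, range 2.07e-05 to 0.851). FKBP14, a prolyl isomerase of the ER, fell 4.84-fold and EDEM3, of ER-associated degradation, 4.34-fold. Among N-glycosylation genes, 12 of 15 fell and 0 rose (adjusted p = 0.0187, with an estimated correlation adjusted p = 0.851, range 0.000678 to 0.851). FUT8 fell 3.69-fold and the galactosyltransferase gene B4GALT1 2.48-fold. The N-glycosylation list lost its call in normexp with repaired background values. Of 14 plasma cell genes, 10 fell and 2 rose, and the list was not called (adjusted p = 0.115). TNFRSF13B, the receptor TACI, fell 8.28-fold and FAM46C 7.9-fold (log2 change -2.98, -3.49 to -2.29 over alternatives). CXCR4 rose 7.53-fold (log2 change 2.91, 0.46 to 3.25 over alternatives) and CD38 3.1-fold. The call of CD38 was lost with array weights (log2 change 1.68, adjusted p = 0.0693) and at 0.32 in normexp with repaired background values (adjusted p = 0.0942), normexp as planned turned it to -1.63, and its adjusted p over alternatives ran from 0.000279 to 0.221.

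Genes that rose strongly from BCL6KO to DKO included EMB (at least 2227-fold), the complement receptor gene CD88 (at least 402-fold), PHYHIPL (at least 401-fold), RDM1 (at least 214-fold), IL1RL1, the receptor for interleukin 33 (adjusted p = 2.3e-06), and CD5, a surface receptor of lymphocytes (adjusted p = 7.13e-08). IL1RL1 and CD5 were well above background on 1 of the 2 BCL6KO arrays. Large falls included those of PARVB (at least 1337-fold), EFNA5 (at least 318-fold), the surface glycoprotein gene CD200 (at least 229-fold), SYNM (at least 194-fold), the sodium channel gene SCN1A (at least 193-fold), the mitochondrial channel gene VDAC1 (at least 156-fold), POPDC3 (at least 143-fold) and DIO2 (adjusted p = 3.21e-05, well above background on 1 of the 3 DKO arrays). VDAC1 was not well above background on any WT array either, and EFNA5 was on 1 of the 3 WT arrays.

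Between DKO and BCL6KO, 16491 genes were called, 6989 higher and 9502 lower in DKO (42.4% higher), with a median of all genes of -0.18. With a symbol, 1479 rose and 1533 fell. The share that rose was 50.3% with scaling by the median and 50.9% with cyclic loess, and the count was 8113 with a minimum fold of 1.5. Beside the genes named above, normexp as planned ended the calls of CD88, PHYHIPL, SPI1, RDM1, F2RL1, CDK6, STIM1, CXCR4 and the lists of ER folding and N-glycosylation. With the repaired values all of these but the N-glycosylation list were called in the direction given. Here too the scan session cannot be told apart from the genotype.

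**Figure D3:**
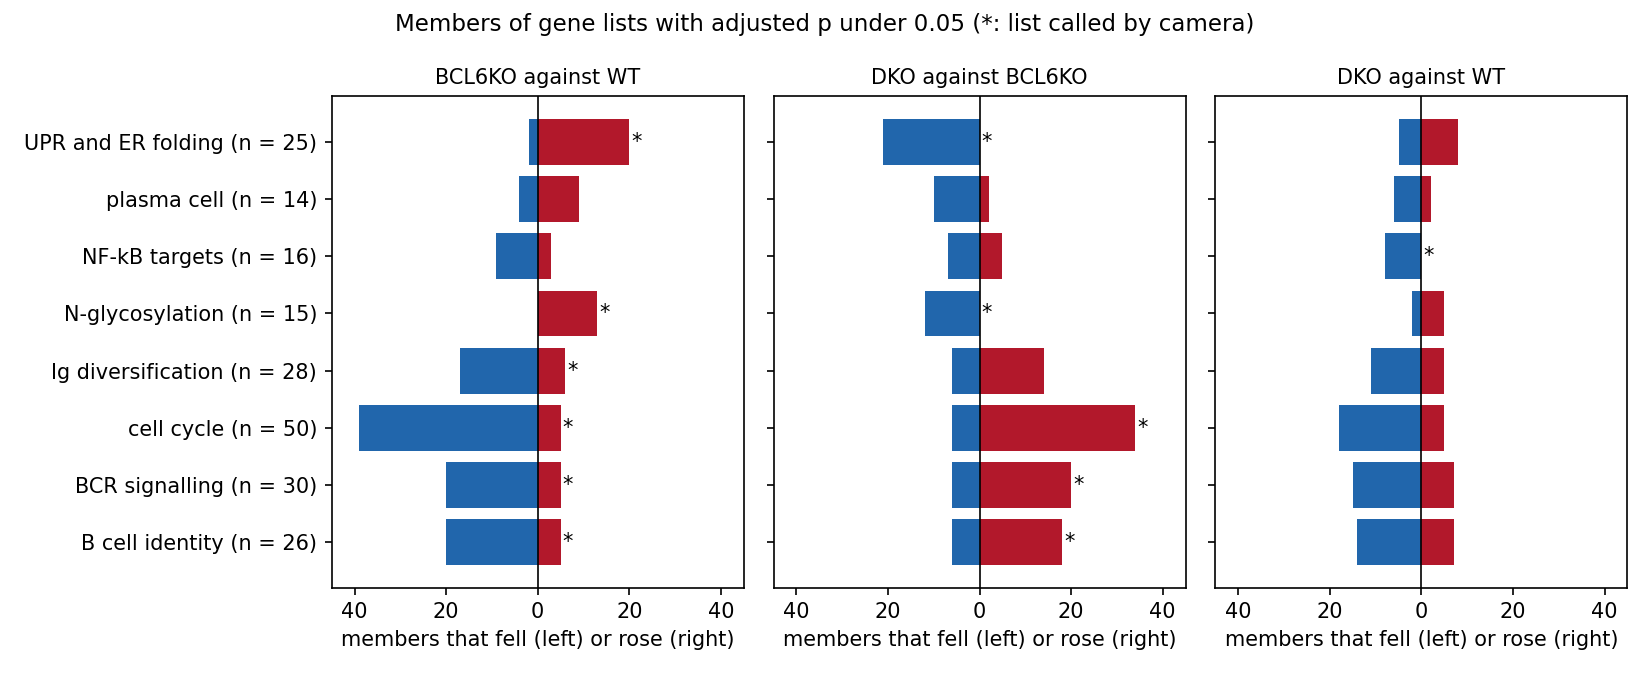
Number of members of each gene list that rose (bars to the right) or fell (bars to the left) with adjusted p under 0.05 in the 3 contrasts, for lists called in any contrast and the plasma cell list, with n the members tested and a star where camera called the list. Of 50 cell cycle genes 39 fell in BCL6KO against WT and 34 rose in DKO against BCL6KO, while of 25 ER folding genes 20 rose in the former contrast and 21 fell in the latter.

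The comparison of DKO with WT asks what changes when IRF4 and BCL6 are both targeted, and its groups shared a scan session. ETV1, an ETS transcription factor, was at least 2842-fold higher, and FABP5, a fatty acid binding protein, was at least 669-fold lower. PAX5 had a log2 change of -0.52 ± 0.14 SE (adjusted p = 0.0191) and JCHAIN one of -0.30 ± 0.09 (adjusted p = 0.031). The call of PAX5 was lost without any of WT arrays 1 and 3 or DKO arrays 1, 2 and 3 (log2 changes -0.53 to -0.49), and that of JCHAIN without any of WT arrays 1, 2 and 3 or DKO array 1 (-0.32 to -0.20). JCHAIN also lost it under quantile normalization (adjusted p = 0.0519), without a filter on dim probes (0.0534), with the replicate number as a block (0.0665) and, within the slides that held both groups, with the slide as a fixed block (0.085), an alternative chosen after seeing the data. Normexp as planned and a minimum fold of 1.5 called neither gene, and over alternatives the adjusted p ran from 7.38e-05 to 1 for PAX5 and from 0.00599 to 1 for JCHAIN. EBF1 (0.26 ± 0.41, adjusted p = 0.639), XBP1 (0.31 ± 0.15, adjusted p = 0.132) and MYC (0.02 ± 0.08, adjusted p = 0.881) were not called. Leaving either BCL6KO array out of the shared fit, or both, called EBF1 (adjusted p = 0.00261, range over alternatives 0.00261 to 1) and XBP1 (0.00311, range 0.00306 to 1) at the same changes, and array weights called XBP1 as well, while MYC turned to -0.13 with scaling by the median, to -0.015 without WT array 2, to -0.0098 without DKO array 1, to -0.038 under quantile normalization and to -0.036 under cyclic loess. Within the 2 slides that held both groups, the log2 difference was -4.74 and -4.64 for IRF4 and -1.91 and -1.71 for BCL6.

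NF-kB targets were the only list of 23 called, with 8 of 16 lower and 0 higher (camera adjusted p = 0.00946, with an estimated correlation adjusted p = 0.493, range over alternatives tested with camera 0.0017 to 0.493). LITAF, a regulator of inflammatory cytokine genes, had a log2 change of -8.54 ± 0.18, and IRF1, an interferon regulatory factor, fell (adjusted p = 2.87e-05) and was well above background on 2 of the 3 DKO arrays. Of 14 plasma cell genes, 6 fell and 2 rose (adjusted p = 0.550). CREB3L2 rose 32.5-fold (log2 change 5.02, 3.76 to 5.14 over alternatives) and SUB1 6.04-fold, while FNDC3A fell 5.44-fold and FAM46C 4.03-fold. Of 26 B cell identity genes, 14 fell and 7 rose (adjusted p = 0.0705). TLR7 fell 113-fold (log2 change -6.82, -6.97 to -5.56 over alternatives) and ID3, an inhibitor of E2A factors, 6.83-fold (-2.77, -2.92 to -1.72), while CHIR-AB1 was at least 74-fold higher and CD72 rose 3.63-fold, a call that normexp as planned ended. In the ER folding list 8 of 25 rose and 5 fell (adjusted p = 0.707), SEL1L rising 2.76-fold and ERO1B falling 5.71-fold.

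Genes with large rises included ETV1, IL1RL1 (at least 1167-fold), EDIL3 (at least 1056-fold), the crystallin gene CRYBB1 (at least 359-fold), PHYHIPL (at least 187-fold), the corepressor gene RUNX1T1 (at least 96.6-fold), the calpain gene CAPN3 (at least 79.2-fold) and the matrix protease gene MMP2 (at least 68.7-fold). Those with large falls included FABP5, MOXD1 (at least 395-fold), DFNA5 (at least 178-fold), KCNK7 (at least 171-fold), CD200 (at least 125-fold), the glutathione transferase gene MGST1 (at least 106.6-fold), LITAF and the growth factor gene MDK (log2 change -8.20 ± 0.17). Over alternatives MDK ran from -8.38 to -7.37.

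In DKO against WT, 12620 of 24136 genes were called, 6889 higher and 5731 lower (54.6% higher), with a median of all genes of 0.07. Of those with a symbol, 1261 rose and 1153 fell. Scaling by the median gave a median of all genes of -0.08 and 41.8% higher, and a minimum fold of 1.5 left 5260 genes. With the WT and DKO arrays fitted alone, 15333 genes were called. The authors' value table, whose columns do not all follow the scanner files of the same label, gave 6875 genes, of which 5378 were also called from the scanner files, 236 of these in the same direction.

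Of the genes changed in BCL6KO against WT, 11885 were changed back in DKO against BCL6KO, 7255 that rose and then fell and 4630 that fell and then rose. Of these, 2190 carried a gene symbol. Among them, those with large changes both ways included PARVB, DIO2 and SYNM, which rose and then fell, and F2RL1 (at least 201-fold higher in DKO than in BCL6KO), RDM1 and CD72, which fell and then rose. By list, 19 of 25 ER folding genes and 12 of 15 N-glycosylation genes rose and then fell, whereas 31 of 50 cell cycle genes, 17 of 30 B cell receptor signalling genes and 16 of 26 B cell identity genes fell and then rose. Of all 24136 tested genes, 7255 rose and then fell and 4630 fell and then rose. Of the 14 plasma cell genes, 8 rose and then fell and 2 fell and then rose. In DKO against WT, 6193 of the 11885 were not called, 3233 were called in the direction of BCL6KO and 2459 in the other. The arrays labelled DKO held 29.7% of the WT signal of BCL6, 46.5-fold more than the BCL6KO arrays. A change back can therefore not be laid to the loss of IRF4 in cells without BCL6.

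Because both contrasts share the BCL6KO arrays, opposite changes arise from their error alone. Independent lists of these sizes would share 5921.58 genes with opposite signs. With no true change, simulation of the shared arrays gave at most 1 shared call in 100 draws and a correlation of changes across genes of -0.601, against -0.650 observed, with a covariance of -0.0505 against -2.08. Where nothing changes, the adjustment lets almost no gene pass in either contrast. The simulated count of shared calls therefore gives no level to set the genes changed back against. With a separate BCL6KO array in each contrast, a test chosen after seeing the data, 11687 genes were changed back with array 1 against WT and 11539 with array 2 against WT. The correlations were -0.586 and -0.607 and the covariances -1.951 and -1.996. Neither the simulation nor the separate arrays cover the scan session. The BCL6KO arrays were alone in theirs, so an effect of the session would also change genes and change them back, and it cannot be told apart from the genotype. Array weights, which set both BCL6KO arrays at 0.171, lowered the count to 7597, and a minimum fold of 1.5 gave 5023.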

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

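Tests of the value table columns, of BCL6 in the DKO-labelled arrays, of dim probes and of cyclic loess were chosen only after the results were seen, whereas those of the scan session and the splits of the arrays were not.

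In the authors' value table, which the comparisons do not use, IRF4 was 5.15 log2 units higher in the columns labelled DKO than in those labelled WT, and BCL6 was 1.56 higher. Both drew attention because a signal of the targeted genes stood above that of the control columns. IRF4 read 14.8 ± 0.39 (SD, n = 3) in the DKO columns, 9.61 ± 0.06 (n = 3) in the WT columns and 16.3 ± 0.28 (n = 2) in the BCL6KO columns, in log2 units of the table. BCL6 read 13.7 ± 0.06, 12.2 ± 0.13 and 6.58 ± 0.31. The columns labelled WT were normalized apart from the other 5, with medians of 7.81 and 7.83, so differences between the sets also carry their normalization.

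The columns labelled WT do not follow the arrays labelled WT. A normalization that changed the order of probes is argued against, since their highest Spearman rho with their own arrays, across probes, was 0.931 while that with an array labelled DKO was 1. All 3 followed a DKO-labelled array of the same replicate number at a rho above 0.99, which is consistent with labels of columns and scanner files that disagree in the deposit. That the arrays and not the columns carry the wrong label is argued against by IRF4, which differed by -4.73 log2 between arrays labelled DKO and WT. By the test set for it, whether the columns labelled DKO hold cells with both genes stays open. Of genes over 2 log2 apart between WT and DKO arrays, 74.9% lay nearer WT in the mean of these columns, between the bounds. Column 1 alone gave 65.7%, column 2 77.4% and column 3 77.3%. Columns 2 and 3 followed the WT arrays at a rho of 0.966 to 0.970 and the DKO arrays at 0.935 to 0.936. Column 1 gave 0.848 to 0.851 and 0.823 to 0.824. These columns thus lay nearer the WT than the DKO arrays, but no array matched any of them (best rho 0.851 to 0.970). IRF4 read 14.8 log2 in the columns labelled DKO, against 9.61 in the columns that follow DKO arrays, a set normalized apart. BCL6 read 13.7 there, against 6.58 in the BCL6KO columns of the same set. Signal of both genes was thus present in the columns labelled DKO, but no array shows which cells they hold.

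BCL6 signal in the arrays labelled DKO lay far above that in the BCL6KO arrays. Admixed WT cells would bring IRF4 and BCL6 alike, yet the percent of WT for BCL6 was 7.90 times that for IRF4, above the bound of 4, which argues against them. Whether the cells lack IRF4 alone stays open. The extraction protocol names IRF4KO cells and no DKO cells, but it does not name the BCL6KO cells either and so does not settle this. The 3 BCL6 probes measured in every group fell within 0.14 log2 of each other, but that comparison leaves out the probe that lost its signal, at least 21.3-fold below WT, and over all 4 probes the changes lay at least 2.67 log2 apart. The 4 probes did not fall alike, and neither a change of transcript in cells without IRF4 nor a BCL6 transcript still made from a disrupted locus was tested. The same 3 probes stood at 0.64% to 0.71% of WT in BCL6KO and at 26.9% to 29.7% in DKO. A disrupted locus would thus have to yield far more transcript in DKO than in BCL6KO.

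More genes rose than fell in the BCL6KO arrays. Dim probes that read higher there may contribute, since 53.4% of called genes rose among those well above background on all 8 arrays, against 60.3% of all called genes, and in 5 equal classes by signal the dimmest genes had a median change of 0.96 against -0.07 for the brightest. This stays open, as the value lies between the bounds for and against. The filter on all 8 arrays also drops genes that rose from background or fell to it. Part of the lower share can thus come from the filter itself. Cyclic loess gave 49.5%, but it centres the differences itself and so decides nothing about a session that differs in the low range. The scan session, slides and extraction version of the BCL6KO arrays held 0 arrays of other groups, so session and loss of BCL6 cannot be told apart.

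The 12620 genes of DKO against WT were set beside the 10 ways to split the 6 arrays into groups of 3. Only 1 split, the real one, gave as many genes, the highest of the others gave 0, and 10 splits are too few for a share under 0.05. Every other split mixed WT and DKO arrays, which puts the difference between these groups into the spread. A low count there was thus fixed beforehand, and the splits decide nothing.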

How the results depend on the processing

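Cyclic loess, the slide as a fixed block, the repaired normexp and separate BCL6KO arrays were chosen after seeing the data, and all other alternatives were planned. Leaving out an array gave 15321 to 17619 genes for BCL6KO against WT, 10775 to 15333 for DKO against WT, 15056 to 17449 for DKO against BCL6KO and 10894 to 12809 changed back, with 6 to 8, 1 to 2 and 5 to 7 lists called. When an array of BCL6KO is left out, the lone array is assumed to vary like the other groups. Of 1056 values of single genes and lists under these settings, 1039 kept direction and call, 10 lost and 5 gained a call and 2 reversed, both MYC in DKO against WT (-0.0098 without DKO replicate 1 and -0.015 without WT replicate 2, in a range of -0.015 to 0.058). Under alternatives other than the value table, the planned normexp, the estimated correlation and left-out arrays, 1661 of 1683 kept direction and call, 15 lost and 4 gained one and 3 reversed. These 3 were MYC in DKO against WT at -0.038 with quantile normalization, -0.13 with the median and -0.036 with cyclic loess, a gene with no call. The replicate block gave 15322, 11320 and 14887 genes. The slide as a random block and treat give no list tests.

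A minimum fold of 1.5 left 8604 genes for BCL6KO against WT, 5260 for DKO against WT, 8113 for DKO against BCL6KO and 5023 changed back, by its stricter null. Array weights set the BCL6KO arrays at 0.171. They gave 11910 genes for BCL6KO against WT, 15967 for DKO against WT, 11324 for DKO against BCL6KO and 7597 changed back. Separate BCL6KO arrays in each contrast gave 11687 and 11539 changed back. Lists called in DKO against WT, 1 in the report, numbered 2 with the median, array weights or the mean of probes, 4 without a filter, 3 with the filter on all 8 arrays and 5 with the repaired normexp. The cause was not tested. An estimated correlation called 0 lists in each contrast and fry 20, 17 and 19 for BCL6KO against WT, DKO against WT and DKO against BCL6KO. Fry tests against no change and compares no list with other genes. Why the calls were lost with an estimated correlation was not tested. The simulated list of independent genes kept its call, but its camera adjusted p rose with the estimated correlation in each contrast. For BCL6KO against WT it went from 4.42e-50 to 0.00141. The lost calls thus do not by themselves show that genes of these lists are correlated.

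Normexp as planned gave 6876, 2819 and 5933 genes in that order of contrasts, 4204 changed back, and 4 lists in DKO against WT and 8 in DKO against BCL6KO. CDKN2B (1.16) and CD38 (0.56) reversed in BCL6KO against WT, and XBP1 (0.19), PAX5 (-0.024) and CD38 (-1.63) in DKO against BCL6KO, and 30 of 132 values lost their call. BCL6KO array 1 held 18 spots with a background over 10 times its median of 23.5, up to 157242, and setting these to the median gave 18903, 13731 and 18030 genes, so they account for the lower counts.

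The authors' value table gave 8304, 6875 and 7007 genes, 4360 changed back, and 4 lists in DKO against WT and 8 in DKO against BCL6KO. Its columns labelled WT follow the arrays labelled DKO and were normalized apart, and 42 of 132 values reversed. In BCL6KO against WT these were EDIL3 -3.01, KCNK7 0.20, CCND2 -1.23, CDKN2B 0.23, CHIR-AB1 -4.46, JUN -0.59 and ERO1B 0.63. In DKO against WT they were IRF4 5.15, BCL6 1.56, XBP1 -0.17, JCHAIN 1.18, EBF1 -0.49, ETV1 -13.49, IL1RL1 -10.87, EDIL3 -11.39, CRYBB1 -7.95, PHYHIPL -7.30, RUNX1T1 -6.32, CAPN3 -5.73, MMP2 -6.21, FABP5 9.98, DFNA5 7.64, KCNK7 1.28, MOXD1 8.60, CD200 7.80, MGST1 7.75, LITAF 8.12, MDK 7.29, IRF1 5.45, CREB3L2 -3.19, SUB1 -3.18, FNDC3A 2.41, FAM46C 1.41, CHIR-AB1 -4.71, CD72 -0.54, TLR7 5.23, ID3 2.38, SEL1L -1.71, ERO1B 1.55 and the NF-kB list 0.26. In DKO against BCL6KO they were IL1RL1 -0.41 and CD38 -1.99.

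Signal over background limits the folds of genes not well above background in a group, which are bounds on the processed signal. The fitted changes of those named were smaller in normexp, as for TLR7 in BCL6KO against WT at -3.67 as planned, still called. Such genes made up 2261, 1635 and 2112 of the called genes in BCL6KO against WT, DKO against WT and DKO against BCL6KO.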

Other observations

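Gene groups outside the B cell and secretory lists also held changed members, without a call of their list by camera. Of all tested genes, 69.6% were called in BCL6KO against WT, 68.3% in DKO against BCL6KO and 52.3% in DKO against WT. Changed members by themselves thus set no list apart. In BCL6KO against WT, 15 of 23 sterol and lipid synthesis genes rose and 3 fell (adjusted p = 0.120), and in DKO against BCL6KO 2 rose and 15 fell (0.240), while 8 rose and 2 fell in DKO against WT (0.478). Of 17 genes of the ATF4 and amino acid response, 11 rose and 2 fell in BCL6KO (0.319), 3 rose and 8 fell from BCL6KO to DKO (0.699), and 6 rose and 0 fell in DKO against WT (0.550). Of 25 genes of oxidative phosphorylation, 13 rose and 2 fell in BCL6KO (0.452), 7 rose and 8 fell in DKO against BCL6KO (0.877), and 13 rose and 3 fell in DKO against WT (0.120). Glycolysis and hypoxia genes, 23 measured, gave 14 rises and 6 falls (0.641), 8 and 10 (0.880), and 9 and 4 (0.484) in the same order of contrasts. Among 24 apoptosis genes 10 rose and 6 fell (0.834), 5 and 13 (0.555), and 5 and 7 (0.550). BCL2, an inhibitor of apoptosis held by this list and by that of BCL6 targets, chosen after its values were seen, rose by 3.73 ± 0.08 log2 units (SE) in BCL6KO and by 2.31 ± 0.07 in DKO, both against WT.

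Of 29 BCL6 target genes, 16 rose and 8 fell in BCL6KO against WT (camera adjusted p = 0.638), 13 rose and 11 fell in DKO against BCL6KO (0.484), and 13 rose and 8 fell in DKO against WT (0.596). NF-kB targets gave 3 rises and 9 falls of 16 in BCL6KO (0.0793) and 5 and 7 in DKO against BCL6KO (0.902). Of 15 antigen presentation genes 4 rose and 4 fell (0.699), 4 and 8 (0.995), and 2 and 5 (0.351), with contrasts in the order BCL6KO against WT, DKO against BCL6KO and DKO against WT. In that order the 13 interferon response genes gave 8 and 5 (0.699), 3 and 8 (0.480), and 6 and 4 (0.679), the 43 genes of ER translocation and transport 16 and 8 (0.641), 7 and 16 (0.775), and 14 and 5 (0.511), and the 20 adhesion and migration genes 7 and 6 (0.707), 7 and 11 (0.696), and 6 and 8 (0.478). The 14 genes of MYC and ribosome biogenesis gave 3 and 7 (0.361), 5 and 2 (0.555), and 1 and 3 (0.834). Immunoglobulin diversification genes, 28 measured, gave 14 rises and 6 falls in DKO against BCL6KO (0.120) and 5 and 11 in DKO against WT (0.115). In DKO against WT, 5 of 50 cell cycle genes rose and 18 fell (0.0578), 7 of 30 B cell receptor genes rose and 15 fell (0.103), and 5 of 15 N-glycosylation genes rose and 2 fell (0.775).

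Markers of other cell types were measured in the same way, and none of their lists was called. T and NK cell markers, 10 measured, gave 4 rises and 4 falls in BCL6KO against WT (0.555), 2 and 5 in DKO against BCL6KO (0.745) and 2 and 4 in DKO against WT (0.480). Of 11 myeloid markers 3 rose and 5 fell (0.319), 5 and 1 (0.0920), and 5 and 2 (0.550). Stromal markers, 10 measured, gave 6 and 1 (0.645), 1 and 4 (0.699), and 4 and 0 (0.645). The 7 erythroid and thrombocyte markers gave 3 and 0 (0.550), 2 and 3 (0.995), and 2 and 1 (0.550). The haemoglobin gene HBBA, chosen like the next 3 after its values were seen, rose by 5.48 ± 0.20 log2 units in DKO against WT. HBE rose too and was well above background on 2 of the 3 WT arrays, while HBA1, well above background on 2 arrays of each group, and HBAD (0.11 ± 0.09) were not called.

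The median, the mean and the camera test of some lists not called differed in sign. In BCL6KO against WT, T and NK cell markers had a median of 0.30 and a mean of -1.11, antigen presentation genes 0.19 and -0.78, and adhesion genes 0.03 and -0.27, each with a test toward lower, as for apoptosis genes with 0.08 and 0.05. In DKO against BCL6KO, the medians and means were -0.67 and 0.18 for T and NK cell markers (test toward lower), -0.21 and 0.34 for antigen presentation and -0.50 and 0.83 for erythroid and thrombocyte markers (both toward higher). In DKO against WT they were 0.07 and -0.93 for T and NK cell markers, -0.25 and 0.000155 for plasma cell genes and 0.04 and -0.03 for MYC and ribosome biogenesis (all toward lower), and 0.46 and -0.46 for interferon response genes (toward higher). Counts of list members adjusted over the list alone differed from those over all genes by at most 3 in BCL6KO against WT, 1 in DKO against BCL6KO and 3 in DKO against WT. In the order of these contrasts, camera with an estimated correlation called 0, 0 and 0 of 23 lists, with 2, 1 and 2 at an unadjusted p under 0.05. Fry, which tests whether the genes of a list move one way on balance and compares no list with other genes, called 20, 19 and 17.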
